A study of Mus musculus with 16 samples.

How the data were processed

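Liver RNA from male C57BL/6 mice was measured on Illumina mouse Ref-8 version 1.1 bead arrays. The samples cover wild type, FXR-/- (Nr1h4 deleted), SHP-/- (Nr0b2 deleted) and the double knockout FXR-/-SHP-/-, each at 3 and 5 weeks of age, with 2 arrays per group and 16 arrays in 8 groups. Per the labels, wild-type mice were bought from a supplier and the knockouts were bred in the laboratory. The labels number the arrays of a group as replicates but do not say whether they are separate animals. The array positions place all 8 arrays of 3-week mice on slide 1 and all 8 of 5-week mice on slide 2, so age and slide cannot be separated, while each genotype comparison at 1 age lies within a slide.

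The deposited unnormalized table holds, per the file headers, the mean bead intensity of each probe, the standard error of that intensity over the beads and a detection p-value, which ranks the probe among the negative controls of its array. It was exported with BeadStudio (BSGX 3.2.3 per the file header) without normalization or background subtraction, and the bead numbers, in 16 value columns, were not used here. The deposited processed table holds 1 value per probe and array on a log2 scale, quantile normalized by the authors, since every column had the same distribution with a median of 6.220. Its transform is not stated, and which part comes from scaling, background treatment or a floor stays unknown. Each processed column correlated best with the signal of its own array (r 0.9887 to 0.9953), which fixed the pairing of both tables.

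Intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which uses the detection p-values to infer the negative controls and adds an offset of 16 before taking log2. The table holds 24613 probes besides 858 control probes, and a probe was kept when its detection p was under 0.01 on both arrays of at least 1 group, which left 10998 probes (44.7%). Gene names came from the platform's probe table by Entrez identifier. Of all probes 20984 had 1 gene symbol, 1 had several and 3628 had none. Among the kept probes 9728 had 1 gene, and the brightest probe stood for its gene, which gave 8140 tested genes. No genome build was given with the arrays, so no coordinates are printed. The order of genes along a chromosome was taken from the mouse assembly GRCm38.p6.

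Linear models were fitted with limma (lmFit, contrasts.fit, eBayes with a mean-variance trend) to all 16 arrays with 1 mean per group, which left 8 residual degrees of freedom shared by all comparisons. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each knockout against wild type at each age, the double knockout against each single knockout at each age, the non-additive part of the double knockout (double minus FXR-/- minus SHP-/- plus wild type) at each age, 5 against 3 weeks in wild type, and the difference of each knockout's effect between ages. Where the probe of a gene was detected on neither array of a group, its fold change is given as a bound, computed by raising the undetected arrays to the lowest signal called detected on them and written as "at least".

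The 33 gene lists were fixed before the data were examined. They cover bile acid synthesis and conjugation, canalicular export, sinusoidal uptake, basolateral efflux, reported FXR target genes, steroid hormone metabolism, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation with PPAR-alpha targets, CAR and PXR targets, NRF2 targets and the cell cycle. Further lists hold markers of cholangiocytes, stellate cells and matrix, macrophages and neutrophils, lymphocytes, erythroid cells, endothelium, hepatocytes, exocrine pancreas, adipose tissue and skeletal muscle. The rest are the acute phase response, gluconeogenesis and amino acid catabolism, male-biased and female-biased liver genes, perinatal liver genes, ER stress with ATF4 targets, immediate early and heat shock genes, circadian clock genes, the interferon response, cytosolic ribosomal proteins and the mitochondrial respiratory chain. The immediate early, heat shock and circadian clock genes were included as markers of handling and time of day. Whether these differed between the groups was not tested. Each list with at least 4 measured members was tested with camera of limma at a preset correlation of 0.01 between genes, again with an estimated correlation, and the p-values were adjusted over the 33 lists of a comparison. Members were counted as risen or fallen with p-values adjusted over all genes, and also with p-values adjusted over the list alone.

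Genes to be named were picked by a fixed rule. It takes Nr1h4 and Nr0b2, the 6 largest rises and 6 largest falls past the threshold whose arrays do not overlap between groups (4 each, with no overlap rule, for the non-additive and age-difference contrasts), and up to 4 members past the threshold per list by size. Up to 2 members are taken where none passed and the list is mentioned. Cyp7a1, Cyp8b1, Cyp17a1 and Abcb11 were always given. For the non-additive and age-difference contrasts a list was marked as differing when camera passed at both correlations and at least 50 percent of its measured members passed. On simulated data of the same size (20 simulations, 200 changed genes each) a change of log2 0.5 was recovered for 56.5% of genes and a change of log2 1.0 for 95.8%, with mean estimates of 0.50 and 1.00, and 5.4% of calls were false. A cell cycle list shifted by 0.5 was called in 20 of 20 simulations, and 1 of 640 unshifted lists was called. The simulated genes varied independently of each other, with the spread between duplicates. These rates therefore do not cover correlated members of a list or any spread beyond that between duplicates.

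The alternatives tried were normexp background correction with an offset of 50, cyclic loess normalization, the authors' values, no detection filter, detection on at least 8 arrays, a fit of only the arrays of the groups compared, the replicate number as a block, the slide as a block and the omission of each array in turn. Chosen after seeing the data were a fit with both ages as replicates of a genotype, counts without genes tracking muscle or pancreas markers (correlation over 0.9 with the list mean), and a fit of each slide alone. Correlations and covariances of log2 fold changes between comparisons that share the 2 wild-type arrays of an age were set against 50 simulations in which no gene changed. A split chosen after seeing the data gave each comparison of such a pair 1 wild-type array, in both assignments. Neighbours of the deleted genes were compared with all other tested genes by Fisher's exact test.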

Results

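The arrays compared livers of wild-type mice with livers lacking FXR (Nr1h4), a nuclear receptor for bile acids, SHP (Nr0b2), a repressor that FXR induces, or both, at 3 and 5 weeks of age. The question was what each loss changes alone, what the loss of both adds, and whether the changes are the same at both ages. There were 8 groups of 2 arrays, from male mice on normal chow. On each array 9597 to 10431 of 24613 probes (39.0% to 42.4%) were detected, the mean signal was 190.1 to 241.1 and the mean of the negative controls was 34.5 to 37.7. The labelling controls of the second double-knockout array were weak at both ages, at 1850.6 and 903.0 for biotin against 2834.2 to 3487.3 on the other arrays. Duplicates differed by 1.26 to 1.32 bead standard errors (SD over probes), or 1.85 and 1.46 in the double knockout at 3 and 5 weeks, while genotypes of 1 age differed by 2.85 to 4.23. The labels do not say that duplicates are separate animals, so p-values measure only the spread between duplicates, and 2 arrays per group limit the precision. Values after ± are standard errors of log2 fold changes with n = 2 arrays per group. A named gene that rose or fell passed an adjusted p of 0.05 over all genes.

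Nr1h4 itself was compared in every group. At 3 weeks its log2 intensity was 10.98 and 10.92 on the wild-type arrays, 11.14 and 11.16 in SHP-/-, 4.55 and 4.30 in FXR-/- and 4.28 and 4.23 in the double knockout, where the probe was not detected. At 5 weeks it was 10.55 and 10.60 in wild type, 11.18 and 11.03 in SHP-/-, 5.91 and 5.97 in FXR-/- and 5.87 and 6.17 in the double knockout, where a low signal was detected. Nr1h4 fell at least 67.6-fold in FXR-/- and at least 70.1-fold in the double knockout at 3 weeks, and 24.80-fold and 23.43-fold at 5 weeks. In SHP-/- Nr1h4 was 0.20 ± 0.11 at 3 weeks (adjusted p = 2.7e-01) and rose by 0.53 ± 0.11 at 5 weeks (adjusted p = 2.6e-03). The probe of Nr0b2 was not detected on both arrays of any group, so the SHP deletion could not be checked by its own transcript.

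Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose in every knockout. At 3 weeks it rose 5.46-fold in FXR-/- (2.45 ± 0.10, adjusted p = 2.6e-12), 1.64-fold in SHP-/- (0.71 ± 0.10, adjusted p = 9.8e-05) and 3.35-fold in the double knockout (1.74 ± 0.10). At 5 weeks the rises were 7.37-fold, 2.61-fold and 8.13-fold. Cyp8b1, which sets the share of cholic acid, rose by log2 1.19 ± 0.08 in FXR-/-, 0.99 in SHP-/- and 1.27 in the double knockout at 3 weeks. At 5 weeks Cyp8b1 rose by 0.73 ± 0.08 in FXR-/-, 0.32 in SHP-/- (adjusted p = 2.1e-02) and 0.65 in the double knockout. Cyp17a1, a steroid 17-alpha-hydroxylase, rose 11.25-fold at 3 weeks (3.49 ± 0.10, adjusted p = 1.4e-14) and 14.75-fold at 5 weeks (3.88 ± 0.10, adjusted p = 8.7e-15) in the double knockout. In SHP-/- Cyp17a1 rose by 0.61 ± 0.10 at 3 weeks and was -0.03 at 5 weeks (adjusted p = 9.1e-01), and in FXR-/- it rose by 0.63 ± 0.10 at 5 weeks. At 3 weeks its log2 intensity was 7.55 and 7.61 in FXR-/-, against 7.19 and 7.23 in wild type. Abcb11, the canalicular bile salt pump, fell 1.95-fold and 1.93-fold in FXR-/- and 2.08-fold and 2.06-fold in the double knockout at 3 and 5 weeks. Abcb11 was 0.13 ± 0.09 (adjusted p = 4.4e-01) and 0.18 ± 0.09 (adjusted p = 2.8e-01) in SHP-/-.

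**Figure D1:**
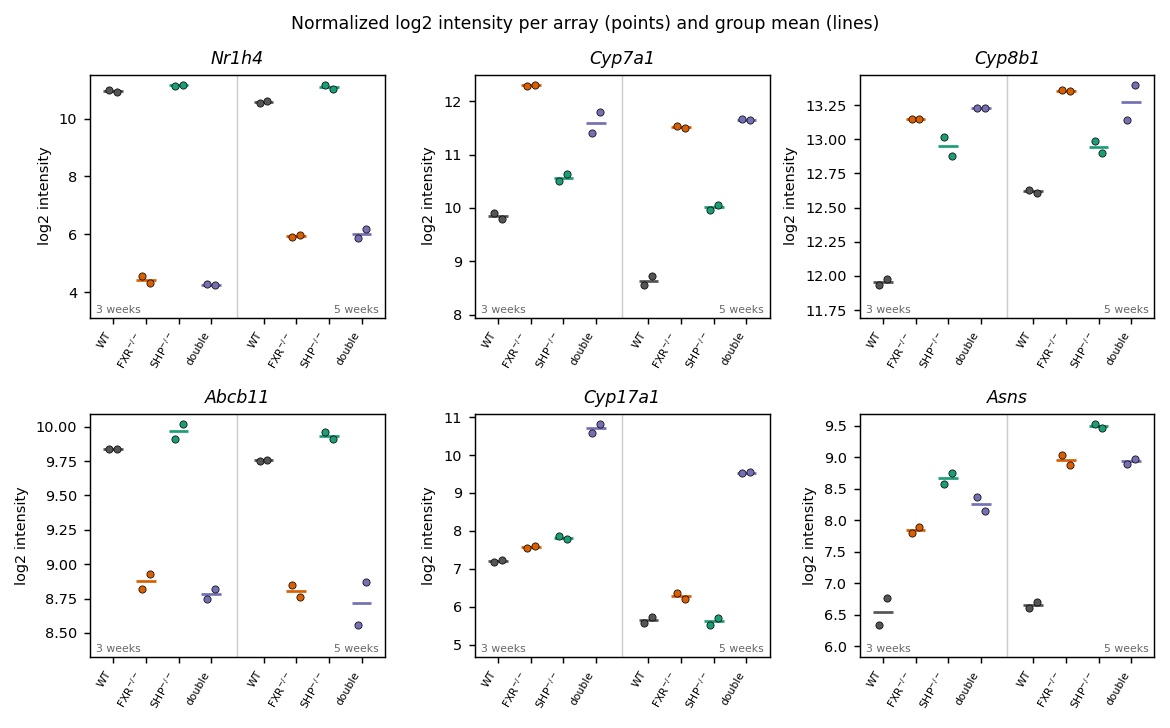
Log2 intensity of Nr1h4, Cyp7a1, Cyp8b1, Cyp17a1 and Abcb11 by genotype and age, with 1 point per array and lines at group means. Cyp17a1 stands apart in the double knockout, 3.49 above wild type at 3 weeks and 3.88 above it at 5 weeks.

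Markers of neighbouring tissues set several groups far apart, but less so the double knockout from wild type at 5 weeks. There the medians were 0.65 for muscle and 0.05 for pancreas genes. The mean log2 intensity of 11 skeletal muscle genes was 4.49 and 4.56 on the wild-type arrays at 3 weeks and was higher at 5 weeks, by a median of 4.23 over the genes. In FXR-/- it was 7.22 and 7.26 at 3 weeks and 4.74 and 4.71 at 5 weeks. The mean of 14 exocrine pancreas genes was 7.52 and 7.51 in wild type at 3 weeks, 5.46 to 5.68 in the knockouts of that age, and 8.83 and 8.84 in SHP-/- at 5 weeks. Acta1, the actin of skeletal muscle, rose by 5.50 ± 0.09 in FXR-/- at 3 weeks and fell by 5.26 ± 0.09 at 5 weeks. Ctrb1, a pancreatic protease, fell at least 17.4-fold in FXR-/- at 3 weeks and rose at least 53.5-fold in SHP-/- at 5 weeks. Tff2, a gastric peptide, was lower by 6.64 ± 0.14 in FXR-/- than in wild type at 3 weeks.

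**Figure D2:**
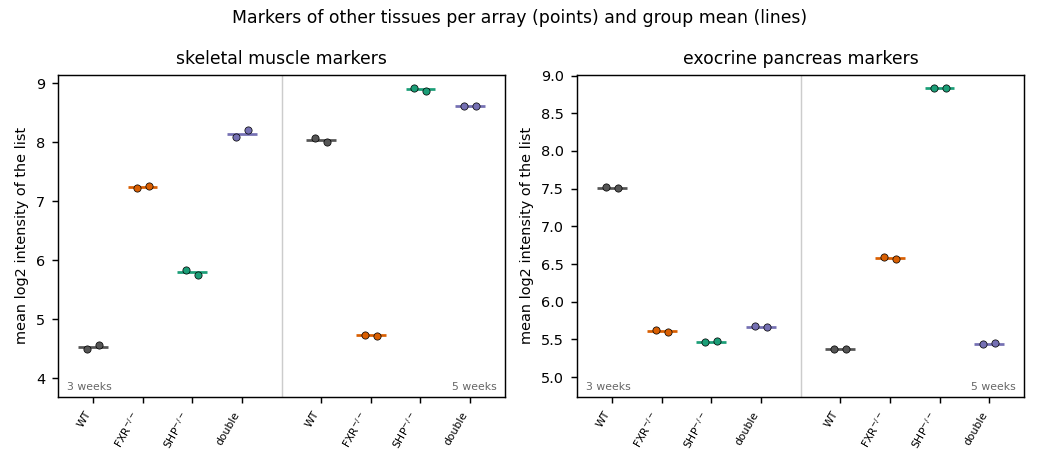
Mean log2 intensity of skeletal muscle and exocrine pancreas markers, 1 point per array, by genotype and age. Duplicates lie close together while groups differ by up to several log2 units, with muscle genes at 4.49 and 8.07 on the replicate 1 wild-type arrays at 3 and 5 weeks.

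Loss of FXR at 3 weeks changed genes of lipid synthesis, the acute phase and proliferation. Pnpla3, a lipid droplet lipase driven by SREBP-1c, rose at least 5.1-fold, Elovl6 rose by 1.70 ± 0.10, Pklr by 1.48 ± 0.09 and Scd1 by 1.13 ± 0.13. Birc5, which guards mitosis, rose by 1.62 ± 0.14 and the mitotic kinase Plk1 by 1.25 ± 0.16. In all, 945 genes rose and 903 fell of 8140, and 331 changed at least 2-fold. Among the largest changes outside other tissues were Cyp2c39 (5.11 ± 0.10), Serpina1e (-5.14 ± 0.08), Ang (a log2 intensity of 5.56 against 10.79) and Mgst1 (-5.88 ± 0.12). Apoh was undetected on both FXR-/- arrays and fell at least 67.1-fold, but at the same age its duplicates had an SD of 4.91 in SHP-/-, where 1 of 2 arrays detected it, and of 2.01 in the double knockout. Hbb-b2, a beta-globin of red cells, rose by 5.02 ± 0.10, while Hbb-bt, another beta-globin looked at after the data were seen, had a log2 intensity of 7.93 in wild type and was undetected in FXR-/-. Cyp2b9 fell at least 15.4-fold. Of 15 measured genes of fatty acid synthesis 14 rose and 1 did not pass (adjusted p = 4.27e-11), and of 24 cell cycle genes 21 rose and 3 did not pass (adjusted p = 3.84e-13). Among 21 acute phase genes 11 rose, 1 fell and 9 did not pass (adjusted p = 4.44e-05), led by Saa2 (2.34 ± 0.12) and Hamp2 (2.33 ± 0.09), and of 14 NRF2 targets 8 rose, as Nqo1 did (0.97 ± 0.14), and 6 did not pass (adjusted p = 1.80e-04). Male-biased genes fell, 10 of 13 against 1 that rose and 2 that did not pass (adjusted p = 3.43e-06), and Cyp4a12b fell at least 9.8-fold and Cyp2d9 by 1.78 ± 0.09. Of the Y-linked genes, looked at after the data were seen, Eif2s3y fell at least 6.9-fold at 3 weeks and at least 4.7-fold at 5 weeks in FXR-/- and was detected in every other group. Kdm5d was undetected in FXR-/- and the double knockout at 3 weeks but detected in every group at 5 weeks, with a log2 intensity of 5.33 in FXR-/-. Immediate early genes rose, 10 of 11 with 1 that fell (adjusted p = 1.23e-09), as in Fos (2.04 ± 0.14) and Jun (1.65 ± 0.15). Counts adjusted over the list alone were the same for these lists. Of 17 reported FXR targets 2 rose and 8 fell, or 4 and 8 adjusted over the list alone, and the list did not pass (adjusted p = 0.082). Among them Apoc2 fell by 2.91 ± 0.12, Slc51b, a basolateral bile salt exporter, fell at least 1.5-fold and Vldlr rose by 2.60 ± 0.13. The female-biased list had 7 rises and 2 falls of 12 (adjusted p = 0.031), with adjusted p = 0.173 with an estimated correlation. CAR and PXR targets had a median of 0.39, a mean of -0.11 and a test toward higher values (adjusted p = 0.233). Beside these changes 10 of 11 muscle genes rose (adjusted p = 3.44e-18) and 14 of 14 pancreas genes fell (adjusted p = 3.27e-20).

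At 5 weeks the FXR-/- livers were higher than wild type in lipid and acute phase genes again, and cholesterol genes joined them. Sqle, an oxygenase of sterol synthesis, rose by 0.98 ± 0.11 and Fdps by 0.88 ± 0.07, and Pnpla3 rose by 2.19 ± 0.13 and Elovl6 by 1.43 ± 0.10. Saa2 rose by 3.95 ± 0.12, Apcs by 2.08 ± 0.12 and Lcn2 by 2.03 ± 0.08. Pck1, the entry enzyme of gluconeogenesis, fell by 1.80 ± 0.15 and its coactivator Ppargc1a by 1.67 ± 0.09. In all, 714 genes rose and 655 fell, 252 of them at least 2-fold. Cholesterol synthesis had 11 rises, 0 falls and 7 not passed of 18 (adjusted p = 9.28e-07), fatty acid synthesis 11, 0 and 4 of 15 (adjusted p = 4.18e-08), both the same adjusted over the list alone. The acute phase list had 12 rises, 0 falls and 9 not passed of 21, or 13 rises and 1 fall adjusted over the list alone (adjusted p = 1.89e-07). NRF2 targets had 7 rises, or 8 adjusted over the list alone, and 7 not passed of 14 (adjusted p = 7.34e-04), led by Gstm3 (1.08 ± 0.18). Lymphocyte markers had 7 rises and 3 not passed of 10, or 8 rises adjusted over the list alone (adjusted p = 1.11e-05), with Ccl5 at 1.12 ± 0.15 and H2-Eb1 at 1.09 ± 0.14. Gluconeogenesis and amino acid catabolism had 5 falls and 5 not passed of 10, or 7 falls adjusted over the list alone (adjusted p = 7.12e-04). Of 8 interferon genes 5 fell and 3 did not pass, the same adjusted over the list alone (adjusted p = 0.001), and Ifit3 fell at least 2.2-fold and Rsad2 by 0.70 ± 0.09. The reported FXR targets had 1 rise and 5 falls of 17, or 2 and 6 adjusted over the list alone (adjusted p = 0.158), with Apoc2 again lower (-2.71 ± 0.12). Cyp4a12b fell (-3.53 ± 0.12) and C6 rose (1.06 ± 0.09), while the male-biased list had 3 rises and 4 falls of 13 (adjusted p = 0.432). Sult2a2, a bile acid sulfotransferase, rose by 3.94 ± 0.10, Dbp, a clock output gene, by 2.29 ± 0.11, and Angptl4, a PPAR-alpha target, fell by 1.11 ± 0.08. Tissue markers moved the other way than at 3 weeks, with 10 of 11 muscle genes lower (adjusted p = 4.49e-26) and 12 of 14 pancreas genes higher (adjusted p = 5.05e-16).

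**Figure D3:**
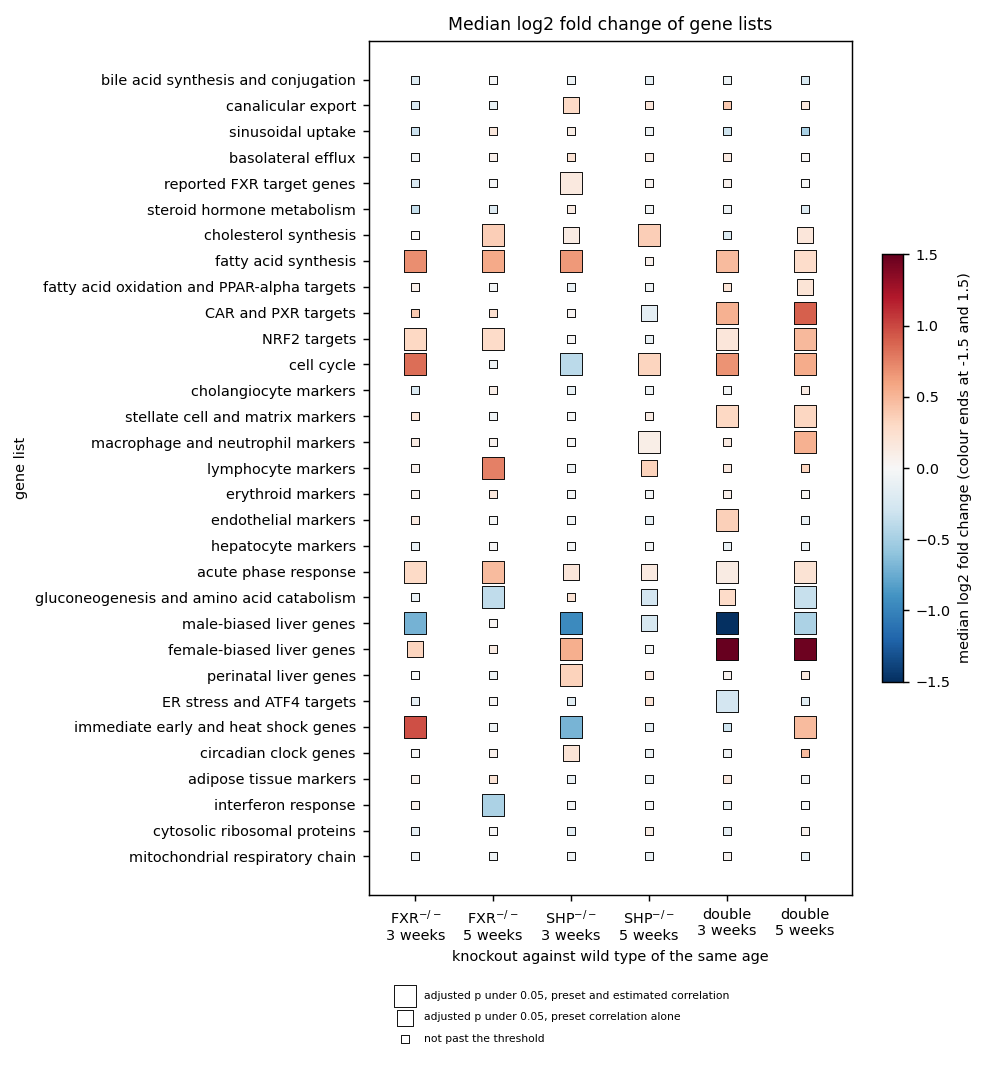
Median log2 fold change of each gene list in each knockout against wild type at 3 and 5 weeks, with lists past an adjusted p of 0.05 marked. The skeletal muscle and exocrine pancreas lists are left out, and the colour scale is cut at both ends. Fatty acid synthesis is higher in all knockouts at 3 weeks, with medians of 0.70 in FXR-/-, 0.65 in SHP-/- and 0.47 in the double knockout.

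Loss of SHP changed fewer genes. At 3 weeks Vldlr rose by 1.88 ± 0.13, Cyp2b10, a target of the xenobiotic receptor CAR, by 1.09 ± 0.15, and the lipogenic genes Scd1 by 0.95 ± 0.13, Thrsp by 0.92 ± 0.12 and Fasn by 0.91 ± 0.16. Asns, a target of ATF4, rose by 2.11 ± 0.12, and Fgf21, a fasting hormone, fell at least 6.6-fold. In all, 504 genes rose and 462 fell, and 125 changed at least 2-fold. Fatty acid synthesis had 11 rises, 0 falls and 4 not passed of 15, or 14 rises adjusted over the list alone (adjusted p = 1.30e-11). Reported FXR targets had 6 rises and 11 not passed of 17, or 7 rises and 1 fall adjusted over the list alone (adjusted p = 0.002), with Sdc1 higher by 0.82 ± 0.10. Cell cycle genes had 1 rise, 12 falls and 11 not passed of 24, or 14 falls adjusted over the list alone (adjusted p = 1.44e-08), with Cdc20 lower by 1.30 ± 0.14 and Aurka at least 1.9-fold lower. Male-biased genes fell, 11 of 13 with 2 not passed (adjusted p = 9.81e-16), as in Cyp4a12a (-2.37 ± 0.09) and Hsd3b5 (-2.45 ± 0.12). Female-biased genes rose, 7 of 12 with 5 not passed (adjusted p = 1.08e-07), as in Cyp2b13 (2.61 ± 0.10) and Cyp2b9 (1.88 ± 0.10). Of 9 perinatal genes 4 rose and 5 did not pass (adjusted p = 0.001), led by Igf2 (1.51 ± 0.12). Immediate early genes fell, 8 of 11 with 1 rise and 2 not passed (adjusted p = 1.02e-07), and Fos fell at least 5.3-fold and Jun by 1.70 ± 0.15. Adjusted over the list alone, the counts of these last 4 lists were the same. Canalicular export (0.002), circadian clock genes (0.014), cholesterol synthesis (0.039) and the acute phase (0.0498) also passed by adjusted p, but not with an estimated correlation (adjusted p = 0.084, 0.084, 0.084 and 0.086). Beside these changes 14 of 14 pancreas genes fell (adjusted p = 5.42e-32) and 7 of 11 muscle genes rose (adjusted p = 3.17e-13).

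At 5 weeks SHP-/- livers had higher cholesterol synthesis genes, with Msmo1 up by 0.99 ± 0.11, Sqle by 0.95 ± 0.11 and Fdps by 0.68 ± 0.07, while Asns rose by 2.85 ± 0.12. Pnrc2, a nuclear receptor coactivator, fell (-3.05 ± 0.15), as did Necap2 (-2.21 ± 0.12) and the adipokine Serpina12 (-1.97 ± 0.09). In all, 402 genes rose and 322 fell, and 88 changed at least 2-fold. Cholesterol synthesis had 10 rises and 8 not passed of 18, or 13 rises adjusted over the list alone (adjusted p = 3.04e-10). Cell cycle genes had 6 rises and 18 not passed of 24, or 10 rises adjusted over the list alone (adjusted p = 1.02e-05), where Cdc20 rose at least 1.7-fold and Plk1 by 0.91 ± 0.16. Macrophage and neutrophil markers had 5 rises and 11 not passed of 16, or 6 rises adjusted over the list alone (adjusted p = 2.42e-04), with the chemokine Cxcl1 at 1.65 ± 0.12 and Marco at 1.08 ± 0.11. Fatty acid synthesis had 1 rise of 15 (adjusted p = 0.323), and reported FXR targets 3 rises and 1 fall of 17 (adjusted p = 0.323). Herpud1 fell by 1.11 ± 0.08 and Creld2, like it an ER stress gene, rose by 1.12 ± 0.08, and the ER stress list did not pass (adjusted p = 0.054). The acute phase (0.012), gluconeogenesis (0.014), lymphocyte (0.028), CAR and PXR (0.038) and male-biased (0.046) lists passed by adjusted p, but not with an estimated correlation (adjusted p = 0.055 for the acute phase and 0.104 for the others). Pancreas genes rose, 14 of 14 (adjusted p = 3.78e-53), and so did 10 of 11 muscle genes (adjusted p = 2.55e-18), with Myh4 up at least 1.3-fold. Fewer genes were called when any of the 4 arrays of a comparison was left out, to a like extent whichever array it was. The same held for FXR-/- at each age.

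Loss of both receptors changed sex-biased and xenobiotic genes, beside the tissue markers. At 3 weeks Cyp4a12a, a male-specific fatty acid hydroxylase, fell at least 27.0-fold, Hsd3b5 fell by 4.94 ± 0.12 and Cyp2d9 by 3.03 ± 0.09, while the female-biased Cyp2b13 rose by 2.76 ± 0.10, Cyp2b9 by 2.01 ± 0.10 and Hao2 by 2.26 ± 0.16. In all, 1095 genes rose and 957 fell, 305 of them at least 2-fold. This total of 2052 was 1326 and 1353 without wild-type replicates 1 and 2, and 1040 with only the compared arrays. Male-biased genes fell, 12 of 13 with 1 not passed (adjusted p = 5.81e-17), and female-biased genes rose, 11 of 12 with 1 not passed (adjusted p = 3.53e-15), both the same adjusted over the list alone. CAR and PXR targets rose, 13 of 19 with 6 not passed, or 15 adjusted over the list alone (adjusted p = 9.90e-10), with Cyp2b10 at 2.17 ± 0.15 and the exporter Abcc3 at 1.33 ± 0.10. Cell cycle genes rose, 17 of 24 with 7 not passed, or 18 adjusted over the list alone (adjusted p = 7.05e-09), with Birc5 at 1.39 ± 0.14. Stellate cell and matrix genes rose, 7 of 18 with 11 not passed, or 11 adjusted over the list alone (adjusted p = 4.22e-04), with Col1a1 at 1.09 ± 0.16 and Vim at 0.77 ± 0.10. Of 16 endothelial genes 10 rose and 6 did not pass, the same adjusted over the list alone (adjusted p = 0.005). Fatty acid synthesis had 8 rises, 2 falls and 5 not passed of 15, or 9 rises adjusted over the list alone (adjusted p = 0.005), with Pnpla3 at least 2.3-fold higher and Elovl6 up by 1.30 ± 0.10 but Thrsp down by 0.87 ± 0.12. ER stress genes had 2 rises, 8 falls and 6 not passed of 16, or 9 falls adjusted over the list alone (adjusted p = 0.011), where Chac1 fell by 1.94 ± 0.13 and Asns rose by 1.71 ± 0.12. The acute phase had 8 rises, 1 fall and 12 not passed of 21, the same adjusted over the list alone (adjusted p = 0.009), with Hamp2 at 2.29 ± 0.09. Gluconeogenesis passed with an adjusted p of 0.013, but had adjusted p = 0.084 with an estimated correlation. Muscle genes rose, 10 of 11 (adjusted p = 8.22e-22), and 13 of 14 pancreas genes fell (adjusted p = 1.29e-18).

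At 5 weeks Sult2a2 rose by 6.93 ± 0.10 in the double knockout, Cyp2b13 at least 22.2-fold and Cyp2b9 by 4.99 ± 0.10. The glutathione transferases Gsta1, Gsta2 and Gstm3, which detoxify electrophiles, rose by 2.57 ± 0.15, 2.48 ± 0.12 and 2.15 ± 0.18. Cyp4a12b, a male-biased gene, fell by 5.18 ± 0.12. In all, 1134 genes rose and 854 fell, 232 of them at least 2-fold. CAR and PXR targets rose, 15 of 19 with 4 not passed (adjusted p = 4.79e-14), female-biased genes rose, 10 of 12 with 2 not passed (adjusted p = 5.60e-13), and male-biased genes fell, 9 of 13 with 4 not passed (adjusted p = 8.14e-08). NRF2 targets rose, 8 of 14 with 6 not passed (adjusted p = 1.47e-04), with Srxn1 at 1.09 ± 0.09, and so did macrophage and neutrophil markers, 11 of 16 with 5 not passed (adjusted p = 2.80e-08), with S100a8 at 2.10 ± 0.12 and Cxcl1 at 1.87 ± 0.12. Adjusted over the list alone, the counts of these 5 lists were the same. The acute phase had 10 rises and 11 not passed of 21, or 11 rises and 1 fall adjusted over the list alone (adjusted p = 3.08e-05), with Saa2 at 2.74 ± 0.12 and Lcn2 at 2.34 ± 0.08. Cell cycle genes had 14 rises and 10 not passed of 24, or 15 adjusted over the list alone (adjusted p = 5.93e-05), with Prc1 at 1.54 ± 0.18. Stellate cell and matrix genes had 11 rises, 1 fall and 6 not passed of 18, or 12 rises adjusted over the list alone (adjusted p = 0.005), with Timp1 at 1.20 ± 0.13. Fatty acid synthesis had 8 rises and 7 not passed of 15, or 8 and 1 fall adjusted over the list alone (adjusted p = 0.006), with Pnpla3 at 2.06 ± 0.13. Gluconeogenesis had 1 rise, 7 falls and 2 not passed of 10, or 8 falls adjusted over the list alone (adjusted p = 0.003), with Pck1 lower by 1.12 ± 0.15. Immediate early genes had 8 rises, 2 falls and 1 not passed of 11, the same adjusted over the list alone (adjusted p = 1.47e-04), where Fos rose at least 4.2-fold and Jun by 1.97 ± 0.15. Cholesterol synthesis had an adjusted p of 0.043, but 0.083 with an estimated correlation. Fatty acid oxidation had an adjusted p of 0.049999, but 0.090 with an estimated correlation and 0.053 with the replicate number as a block. Of the tissue markers 9 of 11 muscle genes rose (adjusted p = 1.62e-06), while pancreas genes had 2 rises and 1 fall of 14 (adjusted p = 0.866).

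What the second deletion added was tested against each single knockout. Against FXR-/-, the double knockout had Cyp17a1 8.70-fold higher at 3 weeks (3.12 ± 0.10) and 9.51-fold higher at 5 weeks (3.25 ± 0.10), and Cyp2b9 at least 62.2-fold and at least 39.6-fold higher. Cyp7a1 was 1.63-fold lower at 3 weeks (-0.70 ± 0.10, adjusted p = 9.2e-05) and 0.14 ± 0.10 at 5 weeks (adjusted p = 3.9e-01). In all, 1241 genes differed at 3 weeks and 1586 at 5 weeks. The 3-week count was 716 and 694 without FXR-/- replicates 1 and 2, 1888 without double-knockout replicate 1, and 534 with only the compared arrays. Male-biased genes were lower, 8 of 13 at 3 weeks (adjusted p = 9.81e-12) and 9 of 13 at 5 weeks (adjusted p = 2.98e-07). Female-biased genes were higher, 6 of 12 (adjusted p = 9.26e-08) and 8 of 12 (adjusted p = 2.13e-11), and fatty acid synthesis was lower, 11 of 15 (adjusted p = 9.26e-08) and 6 of 15 (adjusted p = 0.004), with Thrsp at -1.57 ± 0.12 at 3 weeks. Fatty acid oxidation was higher at 5 weeks, 9 of 17 with 1 lower (adjusted p = 5.96e-05), and Cyp4a14 rose by 2.96 ± 0.08. Immediate early genes were lower at 3 weeks, 8 of 11 (adjusted p = 1.28e-11), and higher at 5 weeks, 9 of 11 (adjusted p = 4.08e-10), with Egr1 at -2.28 ± 0.10 and 1.63 ± 0.10. Interferon genes were higher at 5 weeks, 6 of 8 (adjusted p = 9.17e-04), with Rsad2 at 1.04 ± 0.09. The acute phase list at 3 weeks had a median of 9.67e-04, a mean of -0.25 and a test toward lower values (adjusted p = 0.012). Reported FXR targets at 5 weeks had a median of -0.02, a mean of 0.28 and a test toward higher values (adjusted p = 0.048), with adjusted p = 0.106 with an estimated correlation and 0.053 with the replicate number as a block. Muscle genes were higher at both ages, 10 of 11 each (adjusted p = 6.85e-13 and 3.29e-27), and 13 of 14 pancreas genes were lower at 5 weeks (adjusted p = 6.71e-16). Fcer1g, Mgst1 and Serpina1e, which fell in FXR-/-, were higher in the double knockout than in FXR-/- at 3 weeks. The difference was at least 6.2-fold for Fcer1g, 5.12 ± 0.12 for Mgst1 and 5.01 ± 0.08 for Serpina1e. The Y-linked Eif2s3y was undetected in FXR-/- at 3 weeks and had a log2 intensity of 7.26 in the double knockout. Whether the loss of SHP or another difference of the FXR-/- mice gave these values was not tested.

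Against SHP-/-, the double knockout had Cyp17a1 7.37-fold higher at 3 weeks (2.88 ± 0.10) and 15.07-fold higher at 5 weeks (3.91 ± 0.10), and Cyp7a1 2.04-fold and 3.12-fold higher. Abcb11 was lower by 1.18 ± 0.09 and 1.22 ± 0.09. In all, 2019 genes differed at 3 weeks, or 1056 with only the compared arrays, and 1773 at 5 weeks, or 1129 and 1163 without SHP-/- replicates 1 and 2. CAR and PXR targets were higher, 11 of 19 at 3 weeks (adjusted p = 2.14e-06) and 17 of 19 at 5 weeks (adjusted p = 9.05e-19), with Cyp2c55 at 1.82 ± 0.13 and 3.68 ± 0.13. Cell cycle genes were higher at 3 weeks, 22 of 24 (adjusted p = 1.09e-16), with Birc5 at 2.28 ± 0.14, but at 5 weeks 3 were higher and 1 lower (adjusted p = 0.511). Cholesterol synthesis was lower, 10 of 18 (adjusted p = 7.10e-04) and 5 of 18 (adjusted p = 0.003), with Mvd at -0.92 ± 0.12 at 3 weeks, and fatty acid oxidation was higher, 7 of 17 at each age (adjusted p = 8.38e-04 and 6.24e-04). Stellate cell and matrix genes were higher at 3 weeks, 12 of 18 (adjusted p = 5.52e-06), with Mmp2 at 1.11 ± 0.12, and so were 7 of 16 endothelial genes (adjusted p = 7.10e-04), as in Clec4g (0.74 ± 0.09). NRF2 targets were higher at 5 weeks, 9 of 14 (adjusted p = 2.84e-06), with Gstm3 at 2.75 ± 0.18. Male-biased genes were lower, 8 of 13 with 1 higher at each age (adjusted p = 3.53e-07 and 3.61e-06), and female-biased genes higher, 8 of 12 and 10 of 12 (adjusted p = 1.94e-07 and 3.05e-13). Muscle genes were higher at 3 weeks, 10 of 11 (adjusted p = 8.46e-19), and all 14 pancreas genes were lower at 5 weeks (adjusted p = 2.83e-35). Across the comparisons with wild type 8 of 9, 9 of 13 and 12 of 13 list calls held with an estimated correlation in FXR-/-, SHP-/- and the double knockout at 3 weeks, and 9 of 9, 5 of 10 and 12 of 14 at 5 weeks. At 3 and 5 weeks 10 of 13 and 14 of 15 held for the double knockout against FXR-/-, 9 of 13 and 10 of 12 against SHP-/-, and 4 of 11 and 13 of 15 for the departure from the sum of both losses. For wild-type age 8 of 10 held, and for the age differences in FXR-/-, SHP-/- and the double knockout 11 of 12, 14 of 15 and 9 of 11.

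Whether the double knockout equalled the sum of both single losses was tested on the log2 scale. Cyp17a1 exceeded the sum by 2.51 ± 0.15 at 3 weeks (adjusted p = 1.3e-09) and 3.28 ± 0.15 at 5 weeks (adjusted p = 1.2e-11). Cyp7a1 fell short of it, at -1.42 ± 0.15 (adjusted p = 2.1e-06) and -1.24 ± 0.15 (adjusted p = 7.4e-06), and so did Cyp8b1 at 3 weeks, at -0.91 ± 0.12. For Abcb11 the difference was -0.22 ± 0.13 (adjusted p = 3.3e-01) and -0.27 ± 0.13 (adjusted p = 2.1e-01). In all, 902 genes departed from the sum at 3 weeks (595 without FXR-/- replicate 2, 1389 without double-knockout replicate 1) and 1063 at 5 weeks. Fatty acid synthesis fell short at 3 weeks, 13 of 15 genes (median -0.94, adjusted p = 7.68e-17), with Thrsp at -2.49 ± 0.17 and Fasn at -1.85 ± 0.23. Cholesterol synthesis fell short at 5 weeks, 12 of 18 (median -0.62, adjusted p = 5.18e-10), with Mvd at -1.45 ± 0.18 and Sqle at -1.11 ± 0.15. At 5 weeks CAR and PXR targets exceeded the sum, 11 of 19 (median 0.95, adjusted p = 9.62e-14), as did female-biased genes, 8 of 12 (median 1.20, adjusted p = 7.13e-11), with Cyp2c55 at 5.06 ± 0.19 and Cyp2b10 at 2.34 ± 0.22. Immediate early genes exceeded it at 5 weeks, 9 of 11 (median 0.93, adjusted p = 1.75e-08). Adjusted over the list alone the counts were 14, 13, 12, 8 and 9 in that order. Whether the immediate early genes followed genotype or a difference in handling between groups was not tested. Pancreas genes departed upward at 3 weeks (median 1.65, adjusted p = 9.72e-27) and downward at 5 weeks (median -4.56, adjusted p = 2.33e-43), and muscle genes upward at 5 weeks (median 3.77, adjusted p = 6.16e-20).

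In wild type 608 genes were higher and 695 lower at 5 than at 3 weeks, a contrast in which age and slide coincide. Cyp7b1, an oxysterol hydroxylase, rose by 2.37 ± 0.12, C6 by 2.48 ± 0.09 and Elovl3 by 2.62 ± 0.13, while Cyp2b9 fell by 3.57 ± 0.10, Cyp17a1 by 1.56 ± 0.10 and Cyp7a1 by 1.22 ± 0.10. Fgf21 fell at least 6.5-fold. Male-biased genes rose, 10 of 13 with 3 not passed (adjusted p = 5.31e-15), and female-biased genes fell, 8 of 12 with 4 not passed, or 9 adjusted over the list alone (adjusted p = 1.83e-11). Cell cycle genes fell, 16 of 24 with 8 not passed, or 17 adjusted over the list alone (adjusted p = 1.83e-12), with Mcm5 at -1.31 ± 0.14. Cholesterol synthesis fell, 12 of 18 with 6 not passed, or 15 adjusted over the list alone (adjusted p = 1.92e-08), with Sqle at -1.07 ± 0.11 and Hmgcs1 at -0.87 ± 0.07. Macrophage and neutrophil markers fell, 6 of 16 with 10 not passed, or 7 adjusted over the list alone (adjusted p = 2.24e-05), with S100a8 at -1.33 ± 0.12 and Marco at -1.13 ± 0.11. Ribosomal protein genes fell, 6 of 17 with 11 not passed, or 7 adjusted over the list alone (adjusted p = 0.004), with Rpl13 at -0.63 ± 0.09. Perinatal genes had an adjusted p of 0.043 but 0.159 with an estimated correlation, and immediate early genes 4.58e-04 but 0.059. Muscle genes rose, 10 of 11 (adjusted p = 1.29e-28), and 14 of 14 pancreas genes fell (adjusted p = 1.32e-24). Without any 1 of its 4 arrays the contrast had 810 to 856 genes.

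Effects of the deletions differed between ages for 771 genes in FXR-/-, 630 in SHP-/- and 1003 in the double knockout. Fits without 1 array gave 397 to 448 in SHP-/- and 684 to 1694 in the double knockout, the highest without its replicate 1 at 3 weeks, and fits of only the compared arrays 1016 and 606. The Cyp7a1 effect was larger at 5 weeks by 1.28 ± 0.15 in the double knockout (adjusted p = 6.3e-06), and by 0.67 ± 0.15 in SHP-/- (adjusted p = 7.2e-03), and the difference did not pass in FXR-/- (0.43 ± 0.15, adjusted p = 7.7e-02). The Cyp8b1 effect was smaller at 5 weeks by -0.67 ± 0.12 in SHP-/- and by -0.62 ± 0.12 in the double knockout. Nr1h4 passed in FXR-/- and the double knockout in this contrast, where a residual signal was detected at 5 weeks and not at 3 weeks. A smaller part came from wild type, at 10.98 and 10.92 at 3 weeks and 10.55 and 10.60 at 5 weeks. In FXR-/- cell cycle genes moved down, 17 of 24, or 21 adjusted over the list alone (median -0.90, adjusted p = 7.30e-16), with Birc5 at -1.92 ± 0.19, and so did immediate early genes, 10 of 11 (median -1.14, adjusted p = 1.25e-14), while cholesterol synthesis moved up, 9 of 18, or 11 adjusted over the list alone (median 0.43, adjusted p = 2.05e-06), with Msmo1 at 1.12 ± 0.15. In SHP-/- cell cycle genes moved up, 12 of 24, or 14 adjusted over the list alone (median 0.61, adjusted p = 2.39e-12), with Prc1 at 2.34 ± 0.26, male-biased genes moved up (median 0.69, adjusted p = 4.76e-10), with Cyp4a12a at 2.97 ± 0.13, and female-biased genes down (median -0.58, adjusted p = 1.06e-06). In the double knockout macrophage and neutrophil markers moved up, 8 of 16, or 10 adjusted over the list alone (median 0.58, adjusted p = 4.42e-06), with S100a8 at 2.45 ± 0.17, and gluconeogenesis moved down, 7 of 10, or 8 adjusted over the list alone (median -0.55, adjusted p = 1.02e-05), with Pck1 at -2.14 ± 0.21. The macrophage and neutrophil mean in wild type was 7.26 and 7.27 at 3 weeks and 6.83 and 6.77 at 5 weeks. In the double knockout it was 7.41 and 7.33, then 7.55 and 7.53, so the larger part of its shift came from the fall in wild type. Pancreas genes moved up in all 3 contrasts (medians 2.73, 5.49 and 1.69), and muscle genes moved down in FXR-/- (median -7.35) and the double knockout (median -3.78). These contrasts share the wild-type arrays, where the pancreas mean was 7.52 and 7.51 at 3 weeks and 5.38 and 5.37 at 5 weeks. In the double knockout that mean was 5.68 and 5.66, then 5.44 and 5.45, so its upward shift came from wild type. Its muscle mean was 8.09 and 8.21, then 8.62 and 8.62, while that of wild type rose.

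The overlap of the ages was counted for each genotype. In FXR-/- 352 genes rose and 303 fell at both ages, where independent ages would give 82.9 and 72.7, and 116 changed in opposite ways (155.2 if independent). In SHP-/- 121 rose and 75 fell (24.9 and 18.3 if independent), with 74 opposite (42.8), and in the double knockout 524 rose and 359 fell (152.5 and 100.4), with 99 opposite (248.2). So in SHP-/- opposite changes also exceeded the number for independent ages. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.28 in FXR-/-, -0.01 in SHP-/- and 0.49 in the double knockout, and the rank correlation 0.36, 0.11 and 0.39. With both ages taken as replicates of a genotype, an alternative chosen after seeing the data, 192 genes were called in FXR-/-, 6 in SHP-/- and 205 in the double knockout. The 6 in SHP-/- were Pnrc2, Asns (2.48), Csad (1.89), Eya3, Bsdc1 (-1.58) and Cyp2f2 (-0.82), of which Pnrc2, Eya3 and Bsdc1 lie among the neighbours of Nr0b2 described further on. Of 33 lists 5, 5 and 10 passed in that fit at the preset correlation in FXR-/-, SHP-/- and the double knockout, and 8 and 10 for the double knockout against FXR-/- and SHP-/-. None passed in these 5 comparisons with an estimated correlation (lowest adjusted p = 0.426). In SHP-/- reported FXR targets (0.060), cell cycle (0.755), immediate early (0.433) and female-biased genes (0.062) were among those that did not pass at the preset one. Others called at 1 age or both also did not pass there. Among them were male-biased (0.130) and interferon genes (0.121) in FXR-/-, and ER stress (0.248) and endothelial genes (0.272) in the double knockout. All 3 knockouts changed 38 genes the same way at both ages, where 0.46 would be found if they were independent. They are not independent, since they share wild-type arrays. The largest by mean log2 fold change were Hbb-b2 (3.29), Cyp4a12b (-3.27), Cyp2c39 (2.40), Olig1 (-2.15) and Asns (2.09). Smaller means were those of Cyp7a1 (2.03), Vldlr (1.96), Saa2 (1.96), Csad (1.61) and Bcl6 (-1.35), among others.

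Comparisons with wild type at 1 age share 2 wild-type arrays. At 3 weeks FXR-/- and the double knockout had 560 genes higher in both and 456 lower in both, where independence gives 127.1 and 106.2. Their covariance of log2 fold changes was 0.186, against 0.010 in simulations of unchanged genes with shared controls. For SHP-/- and the double knockout at 3 weeks the counts were 234 and 208 (67.8 and 54.3 if independent; covariance 0.094), and for FXR-/- and SHP-/- 189 and 170 (58.5 and 51.3; covariance 0.068). At 5 weeks they were 406 and 297 for FXR-/- and the double knockout (99.5 and 68.7; covariance 0.087), 246 and 134 for SHP-/- and the double knockout (56.0 and 33.8; covariance 0.047), and 173 and 119 for FXR-/- and SHP-/- (35.3 and 25.9; covariance 0.033). FXR-/- and SHP-/- also had opposite changes beyond independence, 153 against 109.5 at 3 weeks and 107 against 60.6 at 5 weeks. The correlations at 3 and 5 weeks were 0.73 and 0.45 for FXR-/- and the double knockout, 0.53 and 0.34 for SHP-/- and the double knockout and 0.39 and 0.23 for FXR-/- and SHP-/-, where unchanged genes gave 0.50 to 0.51. The simulated covariance was 0.010 for every pair. A part of each excess may come from the shared wild-type arrays. With 1 wild-type array for each comparison of a pair, a split chosen after seeing the data, FXR-/- and the double knockout at 3 weeks had 360 genes higher and 277 lower in both (63.1 and 42.5 if independent), and 377 and 270 with the arrays exchanged (65.5 and 39.8). Their correlation was then 0.67 and 0.68 at 3 weeks and 0.39 in both assignments at 5 weeks. For SHP-/- and the double knockout it was 0.47 at 3 weeks and 0.26 and 0.27 at 5 weeks, and for FXR-/- and SHP-/- 0.33 and 0.16. Opposite changes of FXR-/- and SHP-/- again exceeded independence, 96 and 90 against 43.1 and 42.2 at 3 weeks and 82 and 78 against 23.9 and 23.8 at 5 weeks. Both arrays are of the same wild-type group, so anything particular to that group is still shared. Across ages, where no array is shared, the correlation across genes was 0.44 between FXR-/- at 3 weeks and the double knockout at 5 weeks. There 513 genes were higher and 335 lower in both, with 83 opposite. Between FXR-/- at 5 weeks and the double knockout at 3 weeks the correlation was 0.00. Here 255 genes were higher and 217 lower in both, with 231 opposite. In that pair the muscle genes had opposite medians (-3.99 and 4.48). Between FXR-/- at 3 weeks and SHP-/- at 5 weeks the correlation was 0.00, with 138 opposite changes against 155 higher and 79 lower in both. Between FXR-/- at 5 weeks and SHP-/- at 3 weeks it was -0.10, with 190 opposite against 113 and 59. For SHP-/- and the double knockout it was 0.09 (SHP-/- at 3 weeks) and 0.01 (SHP-/- at 5 weeks), with 218 and 170 opposite against 162 and 168 higher and 91 and 79 lower in both. The numbers for independent lists were not computed for these pairs across ages, so neither the shared nor the opposite counts are called an excess.

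Genes beside the deleted ones were compared with the rest, by their order in the mouse assembly GRCm38.p6. Of the 80 tested genes nearest to Nr0b2, 15 (18.8%) changed the same way at both ages in SHP-/-, against 181 of 8059 other genes (2.25%; odds ratio 10.04, two-sided Fisher's exact test p = 5.2e-10, adjusted over 6 comparisons 3.1e-09). In FXR-/- 8 of the same 80 changed (against 8.02% of the others, exact p = 5.3e-01), and in the double knockout 24 (30.0% against 10.65%, exact p = 2.1e-06). Of the 15 genes 14 changed the same way in the double knockout, against 104 of all 196 genes changed in SHP-/-, and 0 in FXR-/-. Pnrc2 was at -2.94 and -3.05 in SHP-/- at 3 and 5 weeks and at -3.23 and -3.52 in the double knockout, and Bsdc1 at -1.67 and -1.49 in SHP-/-. Eya3 fell at least 3.1-fold at 3 weeks and by 1.92 at 5 weeks in SHP-/-, and Extl1 rose by 1.57 at 3 weeks and at least 2.6-fold at 5 weeks. Another of the 15, Fabp3, moved with the muscle genes, also in FXR-/-, where it was at least 11.2-fold higher at 3 weeks and at least 17.2-fold lower at 5 weeks. Of the 80 nearest neighbours of Nr1h4, 5 changed in FXR-/- (6.2% against 8.05%, exact p = 6.8e-01).

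**Figure D4:**
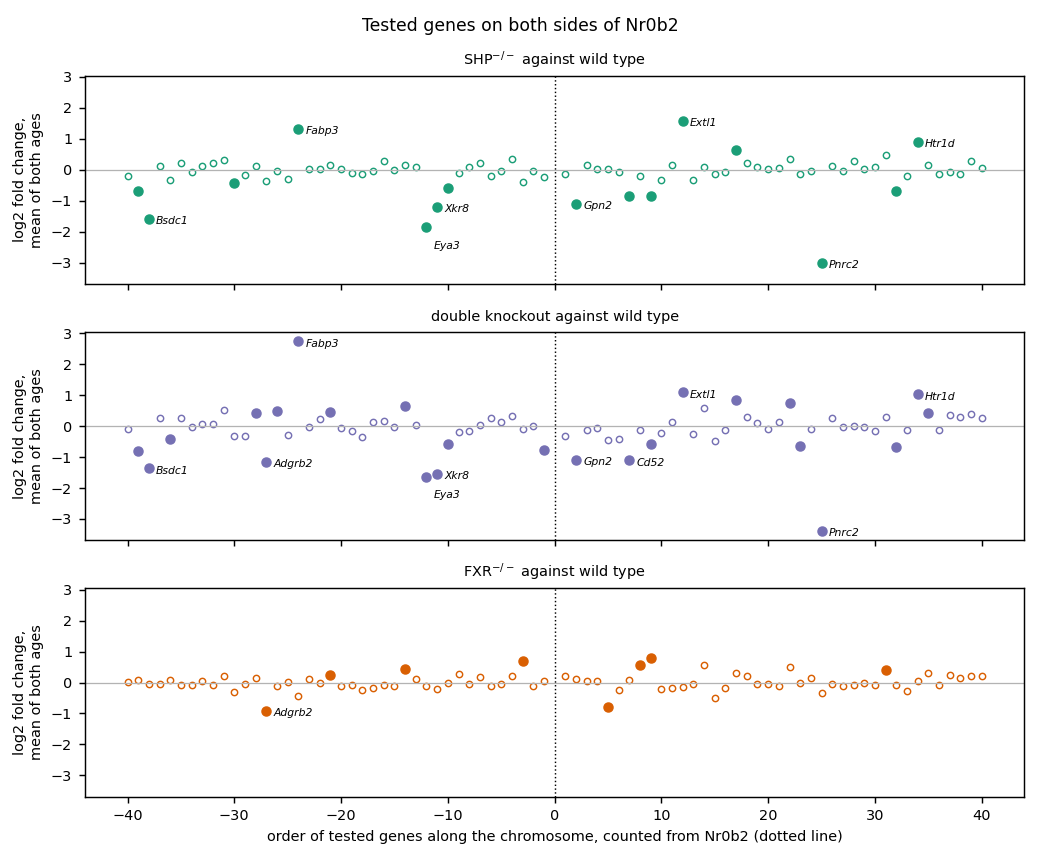
Mean log2 fold change over both ages of the genes nearest to Nr0b2, by their order along the chromosome, in SHP-/-, FXR-/- and the double knockout, with genes changed the same way at both ages marked. In SHP-/- 15 of 80 are marked, 11 of them lower. Undetected probes enter at their measured level.

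Of the 33 lists 9 passed in none of the 16 contrasts. In the double knockout at 5 weeks bile acid synthesis and conjugation had 2 rises and 6 falls of 13 measured genes (adjusted p = 0.374), with Cyp7b1 lower by 1.11 ± 0.12 while Cyp7a1 rose, sinusoidal uptake 1 and 4 of 5 (adjusted p = 0.067) and basolateral efflux 2 and 0 of 5 (adjusted p = 0.345), with Abcc4 up by 1.34 ± 0.14. Steroid hormone metabolism had 2 rises and 3 falls of 8 (adjusted p = 0.913), erythroid markers 2 and 3 of 10 (adjusted p = 0.919), and hepatocyte markers 0 and 2 of 17 (adjusted p = 0.067). Cholangiocyte markers had 1 and 1 of 7 (adjusted p = 0.953), adipose markers 1 and 1 of 4 (adjusted p = 0.962) and the respiratory chain 0 and 5 of 25 (adjusted p = 0.068). In FXR-/- at 3 weeks bile acid synthesis had a median of -0.20, a mean of 0.11 and a test toward lower values (adjusted p = 0.830).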

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

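The results listed here stood out because a test of the difference itself passed, either between the double knockout and the sum of both single losses or between 5 and 3 weeks, or because they lie in probes without a gene name. Chosen only after the result was seen were the tests on the correlation of tissue markers, on the sign of their medians, on the neighbours of Nr0b2 by Fisher's exact test and on the count of genes shared by all 3 knockouts. The interaction tests, the test on second probes and the test on the share of FXR-/- genes were set before their results were seen.

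The double knockout departed from the sum for 902 genes at 3 weeks and 1063 at 5 weeks. At 3 weeks the named departures were Cyp7a1 (-1.42), Cyp8b1 (-0.91), Cyp17a1 (2.51), Apoh (9.25), Tff2 (6.40), Fbxw5 (6.33), Mgst1 (5.25), Chrna4 (-3.62), Dct (-3.49), Cyp2c39 (-3.25) and Cyp2c50 (-2.74). At 5 weeks they were Cyp7a1 (-1.24), Cyp8b1 (-0.40), Cyp17a1 (3.28), Atp2a1 (5.38), Acta1 (5.13), Cyp2c55 (5.06), Erdr1 (4.99), Ctrb1 (-9.82), Cela2a (-6.80), Try4 (-5.75) and Cyp2c39 (-5.70). Lists with such a departure had medians of -0.94 (fatty acid synthesis) and 1.65 (exocrine pancreas) at 3 weeks. At 5 weeks the medians were -0.62 (cholesterol synthesis), 0.95 (CAR and PXR targets), 1.20 (female-biased), 0.93 (immediate early), -4.56 (exocrine pancreas) and 3.77 (skeletal muscle). Where a gene was undetected in a group, as Ctrb1 was in 5 groups, these differences depend on the level of undetected probes and are not bounds. A gene detected in wild type but in neither single knockout must depart upward, whatever the double knockout does. A change of the FXR-/- mice that the double knockout lacks also gives a departure. With both ages as replicates, Mgst1 was at -5.04 in FXR-/- against wild type and Erdr1 at -4.36. In the double knockout against FXR-/- they were at 4.32 and 3.22. Whether the loss of SHP or another difference of the FXR-/- mice gave such departures was not tested. At 3 weeks Apoh was at 12.72 and 5.78 without SHP-/- replicates 1 and 2, whose SD was 4.91, and Fbxw5 at 4.16 and 8.50 without double-knockout replicates 1 and 2. With 1 of 8 arrays left out, Fbxw5 no longer passed in 7 of 8 fits, nor did Cyp8b1 at 5 weeks in 6 of 8.

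The effect of a genotype differed between ages for 771 genes in FXR-/-, 630 in SHP-/- and 1003 in the double knockout. In FXR-/- these included Nr1h4 (1.89), Cyp8b1 (-0.46), Ctrb1 (8.12), Tff2 (7.47), Apoh (7.00), Fbxw5 (6.57), Acta1 (-10.76), Atp2a1 (-9.80), Tnni2 (-9.53) and Fabp3 (-8.50). In SHP-/- they included Cyp7a1 (0.67), Cyp8b1 (-0.67), Cyp17a1 (-0.64), Ctrb1 (11.00), Tff2 (8.83), Reg1 (8.17), Zg16 (8.15), Acta1 (-2.61), Cyp2b13 (-2.50), Hamp2 (-2.29) and Cyp2b10 (-2.12). In the double knockout they included Nr1h4 (2.15), Cyp7a1 (1.28), Cyp8b1 (-0.62), Tff2 (7.75), Dmbt1 (6.06), Sult2a2 (4.90), Prap1 (4.83), Acta1 (-5.90), Atp2a1 (-4.86), Tnni2 (-4.61) and Pvalb (-4.22). The standard errors of Apoh and Fbxw5 in the FXR-/- contrast were 1.81 and 1.87 against 0.13 for Acta1. For Apoh the spread comes from duplicates that differed in SHP-/- and the double knockout at 3 weeks (SD 4.91 and 2.01), groups outside this contrast, and for Fbxw5 among others from FXR-/- at 5 weeks (SD 3.27), within it. Fbxw5 was at 4.26 and 8.88 without FXR-/- replicates 1 and 2 at 5 weeks. With 1 of 8 arrays left out the calls ended in 7 of 8 fits for each of both genes and in 6 of 8 for Cyp8b1 in FXR-/-, and in 3 of 8 for Cyp17a1 in SHP-/-. Differences of genes undetected in a group, such as Fabp3 here, again depend on the level of undetected probes.

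List medians differed between ages in FXR-/- for cholesterol synthesis (0.43), cell cycle (-0.90), immediate early genes (-1.14), exocrine pancreas (2.73) and skeletal muscle (-7.35). In SHP-/- they differed for cell cycle (0.61), male-biased (0.69), female-biased (-0.58), immediate early (0.58) and pancreas genes (5.49). The double knockout differed for CAR and PXR targets (0.40), macrophages and neutrophils (0.58), gluconeogenesis (-0.55), male-biased (1.33), immediate early (1.09), pancreas (1.69) and muscle genes (-3.78). For the immediate early genes, a list included as a marker of handling, a difference in handling between groups stays open and was not tested. Of 1270 probes without a gene name, which no comparison of genes uses, 236, 144 and 279 passed at 3 weeks and 194, 99 and 305 at 5 weeks in FXR-/-, SHP-/- and the double knockout.

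Many of these differences lie in skeletal muscle and exocrine pancreas genes, and a candidate source is RNA of neighbouring tissue in the liver pieces. The members of each list moved together over the 8 group means, with a median correlation of 0.99 for muscle and 0.95 for pancreas, and 9 of 11 muscle and 11 of 14 pancreas genes were undetected in at least 1 group, while 2 and 3 were detected in every group and none is in another list. Acta1, an abundant muscle transcript, ranged from 4.98 in wild type at 3 weeks to 12.03 in SHP-/- at 5 weeks, and Ctrb1 from 4.31 in wild type to 10.65 in SHP-/- at 5 weeks. An effect of the genotype that is the same at both ages is argued against, since 3 of 6 knockout and list pairs turned sign, as in muscle in FXR-/- (3.12 and -3.99) and pancreas in SHP-/- (-1.60 and 3.62). A program that switches these genes on in liver by genotype and age together stays open and was not tested, as does dissection, which the labels do not describe.

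Genes next to Nr0b2 changed in SHP-/- and the double knockout, and a chromosome segment that came with the deleted allele is a candidate explanation. By Fisher's exact test over genes, neighbours were more often changed at both ages in SHP-/- (exact p = 5.2e-10), which was not seen in FXR-/- (exact p = 5.3e-01), and 14 of the 15 changed alike in the double knockout, as did 104 of all 196 genes of SHP-/-. Sequence variants under single probes cannot be told apart from changed transcripts, because only 1 of these neighbours had a second detected probe. That gene was Eya3, whose second probe was at -0.07 and -0.17 at 3 and 5 weeks where the main one was at -1.92 at 5 weeks, so 0 of 1 second probes moved the same way. A regional effect of the loss of SHP itself also stays open, as untested.

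Wild-type mice were bought and knockouts bred, so a difference between the bought WT mice and the bred knockouts could add to every comparison with wild type. If a source common to all 3 knockouts were the whole cause, most genes changed at both ages in FXR-/- should do so in all 3. The share was 5.8%, but this test cannot decide the question. Only 196 genes changed the same way at both ages in SHP-/- against 655 in FXR-/-, so the share could not reach most of them. Nor does the test bear on a difference from the bought mice that is particular to each bred line, which was not tested. A difference between bought and bred mice also stays open for the 38 genes changed the same way in all 3 knockouts. These were 19.4% of those of SHP-/- and 4.3% of those of the double knockout. There the source of the mice and a genotype effect that all knockouts share cannot be told apart, because no bred wild type is among the samples and both predict more than the 0.46 genes of independent lists. The 3 comparisons also share the wild-type arrays of each age, which can raise the number by an amount that was not estimated.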

How the results depend on the processing

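Chosen only after seeing the data were the fit with both ages as replicates, the counts without genes tracking muscle or pancreas markers, the fit of each slide alone and the split of the wild-type arrays between comparisons. Background correction with an offset, cyclic loess, the authors' values, both detection settings, the replicate block and the omission of tracking genes moved no count of genes by over 1.5 times, and no call reversed among the named genes under the other 10 settings run on them or among the lists under 9. Lists were not rerun with the slide as a block, with only the compared arrays or within 1 slide, and calls were not compared one by one with the fit of ages as replicates. The slide as a block says nothing about stability, because slide and age coincide and the group means already hold it, and it is not possible for the wild-type age contrast. The replicate block could move little, since differences between duplicates had a median correlation of 0.00 over 28 pairs of groups. With the replicate block 1846, 950 and 2052 genes were called at 3 weeks and 1376, 731 and 1954 at 5 weeks in FXR-/-, SHP-/- and the double knockout, while 13 of 1687 named gene calls and 2 list calls ended (fatty acid oxidation in the double knockout at 5 weeks and reported FXR targets against FXR-/- at 5 weeks). Of the named gene calls 24, 28 and 33 ended with background offset, cyclic loess and authors' values, 124 without a detection filter and 112 when only the arrays of the groups compared were fitted. Of 195 list calls 38 ended with an estimated correlation. Of the scaling alternatives cyclic loess moved the share of higher genes most, from 56.4% to 64.1% for the double knockout against FXR-/- at 5 weeks.

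Fitting only the compared arrays gave 1040 genes for the double knockout at 3 weeks (2052 with all arrays), 534 against FXR-/- (1241) and 1056 against SHP-/- (2019), and for the age difference 1016 in SHP-/- (630) and 606 in the double knockout (1003). Within its slide alone SHP-/- at 3 weeks had 636 (966). In these fits the spread comes from fewer arrays, by construction. With duplicates averaged and ages as replicates, for which limma had 3 residual degrees of freedom, 192 genes were called in FXR-/-, 6 in SHP-/-, 205 in the double knockout, and 59 and 151 for the double knockout against FXR-/- and SHP-/-, with 1150, 444, 1447, 926 and 1457 at an unadjusted p under 0.05. That fit asks for changes alike at both ages, and its share of higher genes was 33.3% in SHP-/- and 41.1% for the double knockout against SHP-/-.

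Leave-one-out fits assume that the lone sample of a group varies like the other groups. They gave 533 to 559 genes for SHP-/- at 3 weeks and 413 to 425 at 5 weeks, and 810 to 856 for wild-type age, where each of the 4 arrays moved the count. The double knockout at 3 weeks gave 1326 to 2665, with 1326 without wild-type replicate 1, 1353 without wild-type replicate 2 and 2665 without its own replicate 1. Against FXR-/- at 3 weeks it gave 694 to 1888 (716 and 694 without FXR-/- replicates 1 and 2, 1888 without double-knockout replicate 1), and against SHP-/- at 5 weeks 1129 to 1365 (1129 and 1163 without SHP-/- replicates 1 and 2). The non-additive count at 3 weeks was 595 to 1389 (595 without FXR-/- replicate 2, 1389 without double-knockout replicate 1). The age difference was 397 to 448 in SHP-/- (397 without wild-type replicate 2 and 410 without SHP-/- replicate 2 at 3 weeks, and 415, 419 and 405 without wild-type replicates 1 and 2 and SHP-/- replicate 2 at 5 weeks). In the double knockout it was 684 to 1694 (1694 without its replicate 1 at 3 weeks). Leaving out an array lowers the number of samples, but the rises without double-knockout replicate 1 do not follow from that. A group left with 1 array adds nothing to the shared spread. The 3-week double-knockout duplicates, which differed most (1.85 bead standard errors), then drop out of it, which can raise a count. Leaving out replicate 2 drops the same pair, yet every double-knockout comparison had its highest count without replicate 1. That leaves only replicate 2, whose labelling controls were weak. Differences between duplicates correlated at 0.34 between the double knockout at 3 and 5 weeks, the highest of 28 pairs of groups. How much of the rises comes from the spread and how much from replicate 2 was not tested. Over these fits 1152 of 8652 tests of named genes and 47 of 1036 of lists no longer passed. Signal over background limits what can be called, since mean signal was 190.1 to 241.1 against 34.5 to 37.7 for negative controls, and little can be said of undetected probes, Nr0b2 among them. Non-additive and age differences of genes undetected in a group are neither exact nor bounds, since they depend on the level of such probes.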
